A study of Mus musculus with 4 samples.

How the data were processed

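The series holds 4 libraries from sorted T cells and APCs of tumor-draining lymph nodes: 2 RNA libraries (10x 5' chemistry) and the 2 matching TCR libraries, 1 of each per chow. The deposited matrices hold UMI counts per gene and barcode for 32285 genes, made with Cell Ranger 5.0.0 per the file headers. The submitters' processing notes name the mm10 genome and Seurat 5.0.3. The deposited TCR contig tables hold counts of UMIs and reads per assembled contig, in the filtered form of the authors' pipeline. In the annotation tables that the authors deposited for APCs and for T cells, each cell has its UMI and gene counts, a mitochondrial share in percent, cell cycle scores, and a cell type name. The cell cycle score columns are unitless values that the authors computed with Seurat. For T cells the deposited tables add the clonal frequency in counts of cells.

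The annotation tables carry no barcodes. Each annotated cell was therefore joined to a barcode by its values: total UMIs and detected genes over the genes seen in at least 3 barcodes of the library, and the mitochondrial percent. All 5825 annotated cells matched exactly 1 barcode. The annotated cells are 39.2% of control and 34.0% of RGX-104 barcodes, and the authors' doublet column names all of them singlets. All have at least 801 genes and under 5% mitochondrial UMIs. No further filter was applied in the main values.

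Counts were summed over the cells of each library and type, without other normalization than division by the summed total (CPM). The RGX-104 to control ratio of a gene carries an exact conditional binomial 95% interval, a CPM an exact Poisson interval and a share a Clopper-Pearson interval. With 1 library per group no p-value, standard error or count of differing genes was computed. A gene counts as measured with at least 50 UMIs over both libraries in the cells compared. A ratio against a library at 0 is given as a lower bound against a floor of 3 counts in that library. Types were compared where each library had at least 50 cells: 6 of the authors' 10 APC types and 8 of their 12 T cell types.

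The 26 gene lists, the rule for named genes, the intervals and most alternatives were fixed before the data were examined. The lists cover LXR targets, cholesterol synthesis and uptake, type I interferon response, interferon gamma response and class I presentation, class II presentation, the mature migratory dendritic cell program, macrophage lipid handling and efferocytosis, inflammatory cytokines and chemokines, T cell activation, cytotoxic, inhibitory, naive, regulatory and follicular helper T cells, proliferation, glycolysis, oxidative phosphorylation, the dissociation and stress response, and 8 lists of other cell types. A list is described by the median log2 ratio of its measured members (at least 5), an interval from 1000 Poisson draws of the counts, the number of members at least 1.5-fold higher or lower, and the place of its median among 10000 random lists of the same size drawn from 20 bins of expression. These random lists describe the 2 libraries and give no test between chows.

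Named genes are the 8 with the highest and the 8 with the lowest ratio in all APCs and in all T cells, and 3 and 3 in each type. They are ranked by the bound of the interval nearest to 1 among measured genes with at least 20 CPM in 1 library, without receptor segments, immunoglobulin, mitochondrial and ribosomal protein genes and unnamed gene models. To these come up to 4 members of each list with the largest ratio either way, and Abca1, Abcg1, Srebf1, Nr1h3, Nr1h2, Mylip, Apoe, Scd2 and Ccr7 in all cases. Values of lists in APCs without macrophages or without pDC, and in T cells without Cytotoxic T or Bcat1+ T, were chosen after seeing the data, as was naming several genes in single types. Gene positions come from the RefSeq annotation of GRCm38, the assembly behind mm10.

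To count pDC among barcodes without an annotation, 10 markers were used (Siglech, Ccr9, Tcf4, Bst2, Ly6d, Cox6a2, Klk1, Runx2, Smim5 and Cd300c).

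A clonotype is the V gene, J gene and CDR3 nucleotide sequence of the productive TRA and TRB chain with most UMIs, in cells with both. The libraries were compared unthinned and thinned to the same number of cells (mean of 1000 draws). Types were compared with at least 50 paired cells in each library.

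Alternatives for the gene values were TMM factors (edgeR 4.0.16 in R 4.3.3), median-of-ratios factors, totals without receptor, immunoglobulin, mitochondrial and ribosomal protein genes, minimums of 10 and 200 UMIs, the mean over cells of per-cell CPM, the mean over types of their medians, removal of doublets and of cells with transcripts of another lineage, cells thinned to 2000 UMIs, and 2-fold for counting members. Doublets were scored with Scrublet in scanpy 1.11.5. Its automatic threshold marked 0 barcodes, so the 6% of barcodes with the highest scores were removed instead, a choice made after seeing the data. These hold 10 control and 17 RGX-104 APCs and 17 and 7 T cells. Also chosen after seeing the data were leaving out the 1 cell with most UMIs of each gene and CPM averaged over types with the same weights. Shares were recomputed with at least 1000 UMIs and at most 5% mitochondrial UMIs, with all barcodes as denominator, and among T cells with paired chains. Clonotypes were recomputed from TRB alone, from amino acids, from the deposited clonotype number, from chains with at least 3 UMIs, and in subsets of cells.

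The gene ratios were tested on simulated data. Counts with the depth of these libraries were drawn with known changes, and the interval of a changed gene excluded 1 in the right direction for 96.9% of genes changed 1.5-fold in APCs, 97.0% at 2-fold and 100% at 4-fold. The T cell figures were 91.0%, 98.5% and 100%. Among 10160 unchanged genes in APCs the interval excluded 1 for 4.56%. This simulation holds counting noise alone. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.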

Results

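Tumor-draining lymph nodes were taken from mice 8 days after injection of tumor cells. The mice ate control chow or, from day 3, chow with RGX-104, an agonist of the liver X receptors (LXR), the oxysterol-sensing nuclear receptors that control cholesterol export and fatty acid synthesis. From these nodes T cells and cells that present antigen (APCs) were sorted and read by 10x 5' single-cell RNA sequencing, and the T cell receptor (TCR) transcripts of the same cells were sequenced as well. Each chow was represented by 1 RNA library and 1 TCR library, so there are no replicates. The comparison asked how T cells and APCs differed with and without LXR activation. Intervals are 95% counting intervals; they cover counting error only and say nothing of the spread between mice or between libraries.

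The control RNA library held 7346 barcodes and 31530931 unique molecular identifiers (UMIs), with a median of 3276 UMIs and 1318 genes per barcode. The RGX-104 library held 8671 barcodes and 38480769 UMIs, with medians of 3119 and 1277. The authors' annotation named 782 APCs and 2099 T cells in the control library and 949 APCs and 1995 T cells in the RGX-104 library. Median depth was 8052 UMIs in control APCs and 9043 in RGX-104 APCs, and 4944 and 5048 in T cells. Expression is given as CPM, the UMIs of a gene scaled by the UMIs of all genes, both summed over the compared cells of 1 library.

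In APCs, the transcripts of LXR target genes were higher in the RGX-104 library. Abca1, the cholesterol exporter, stood at 6.84 CPM in control APCs and 99.1 CPM in RGX-104 APCs, a ratio of 14.5 (10.9 to 19.7). Scd2, a stearoyl-CoA desaturase of fatty acid synthesis, stood at 22.6 and 223 CPM, a ratio of 9.88 (8.43 to 11.6). Apoe, the lipoprotein that accepts exported cholesterol, stood at 124 and 612 CPM, a ratio of 4.95 (4.61 to 5.31). In APCs other than the cells named macrophages, Abca1 was 14.3-fold higher (10.5 to 20) and Apoe 1.59-fold higher (1.40 to 1.82). Of the 24 fixed LXR targets, all measured in APCs, 18 were at least 1.5-fold higher in the RGX-104 library and 1 was at least 1.5-fold lower, and the median log2 ratio was 1.33 (1.16 to 1.42). The central 95% of 10000 random lists matched on expression ran from -0.15 to 0.05.

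The positions of these genes on mm10, all protein coding, were as follows. Abca1 (ENSMUSG00000015243) lies on chromosome 4 from 53030789 to 53159988, Scd2 (ENSMUSG00000025203) on chromosome 19 from 44293676 to 44306864, and Apoe (ENSMUSG00000002985) on chromosome 7 from 19696244 to 19701310.

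The other LXR targets differed in size. Scd1, the second stearoyl-CoA desaturase, had a log2 ratio of 3.34, and Mertk, a receptor for the uptake of dying cells, one of 3.32, with 1 control and 2 RGX-104 UMIs outside the cells named macrophages. Lpl, lipoprotein lipase, had one of 2.17. Srebf1, the transcription factor of fatty acid synthesis, was 3.72-fold higher (3.10 to 4.48), and Mylip, a ubiquitin ligase induced by LXR, was 2.70-fold higher (2.37 to 3.08). Abcg1, the partner exporter of Abca1, was 2.59-fold higher (2.41 to 2.78). The single member at least 1.5-fold lower was Nr1h3, which encodes LXR alpha, at 15.9 CPM in control and 9.34 CPM in RGX-104 APCs, a ratio of 0.589 (0.443 to 0.780). The cells named macrophages held 68 of its control and 54 of its RGX-104 UMIs. Outside them its ratio was 0.623 (0.398 to 0.971), from 48 and 39 UMIs. Its interval lay below 1 in 1 of the 6 compared APC types. Nr1h2, which encodes LXR beta, had a ratio of 0.995 (0.874 to 1.13), and Ccr7, the chemokine receptor that guides migratory dendritic cells into nodes, one of 0.991 (0.967 to 1.02). In the 6 compared APC types the interval of Ccr7 lay above 1 in 3 and below 1 in 2, with ratios from 0.894 to 1.38.

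Genes of cholesterol synthesis and uptake were also higher in RGX-104 APCs. Of 23 measured members 20 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.81 (0.72 to 0.95) against a random range of -0.16 to 0.07. Sqle, squalene epoxidase, had a log2 ratio of 1.49, Fdps, farnesyl diphosphate synthase, 1.32, and Lss, lanosterol synthase, 1.17. With members counted at 2-fold instead of 1.5-fold, 7 were higher. In cells with both deposited cell cycle scores under 0, which were 82.4% of control and 84.7% of RGX-104 APCs, the median was 0.83 (0.74 to 0.98).

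Both lists had medians above their random range in each of the 6 APC types with at least 50 cells in each library. The types carry the authors' names (mcDC1, mcDC2, rcDC1, rcDC2, mLC and mono), whose abbreviations the deposited tables do not spell out. The LXR target median was highest in mcDC2, at 2.25 (1.46 to 2.77) over 9 measured genes, and lowest in mono, at 0.21 (0.10 to 0.94) over 13. The mono value lay at the edge of its random range, which ended at 0.20, and its members split: Scd2 was 18.2-fold higher (10.0 to 37.0) and Srebf1 7.87-fold higher (3.62 to 20.3), while Pltp and Tgm2 had ratios of 1.02 and 1.04. Its middle gene was Lpl, with 70.4% of the control UMIs from 1 cell. Without the 1 cell with most UMIs of each gene in each library the median of LXR targets in mono was 0.97, and with genes of 10 UMIs or more it was 1.43, so its place as the lowest was not stable. The cholesterol median was highest in mono, at 1.92 (1.23 to 2.18), followed by rcDC2 at 1.91, and lowest in mLC, at 0.38 (0.18 to 0.53). In mcDC2 it was 0.41, with an interval of 0.17 to 0.65 whose lower end lay inside the random range, which ended at 0.24. Abca1, Abcg1, Srebf1 and Scd2 had ratios with intervals above 1 in all 6 types, and Abca1 ran from 6.98-fold in rcDC2 to 90.0-fold in rcDC1, where the control library had 1 UMI (interval 15.8 to 3587).

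**Figure D1:**
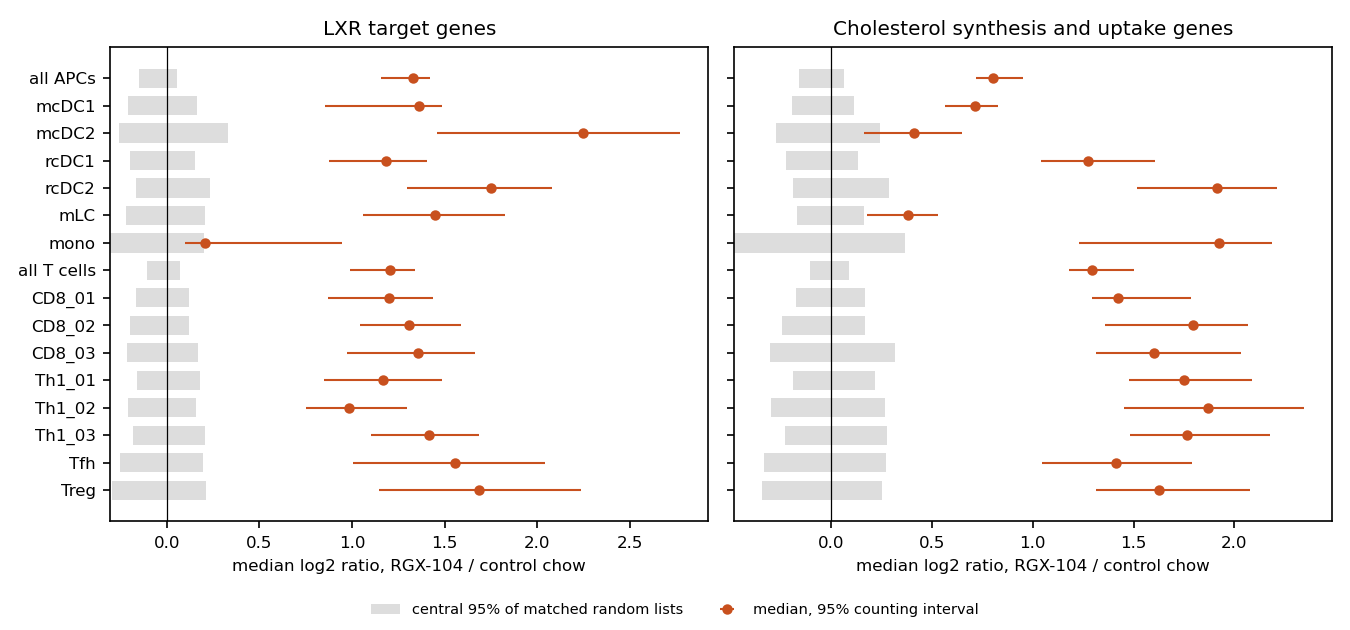
Median log2 ratio of the LXR target list (left) and of the cholesterol synthesis and uptake list (right) in all APCs, all T cells and each compared type, RGX-104 over control library; points are medians, lines their 95% counting intervals and grey bars the central 95% of matched random lists. All points lie to the right of the grey bars, from 0.21 in mono to 2.25 in mcDC2 on the left and from 0.38 in mLC to 1.92 in mono on the right.

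Genes of lipid-handling and cell-engulfing macrophages were higher in RGX-104 APCs. The median log2 ratio of that list was 1.15 (0.87 to 1.60), with 14 of 20 measured members at least 1.5-fold higher and 0 lower. Gpnmb, a membrane glycoprotein of lipid-laden macrophages, was 34.4-fold higher (17.3 to 80.3), with 2 control and 5 RGX-104 UMIs outside the cells named macrophages, and Trem2, a lipid-sensing receptor, had a log2 ratio of 2.46. The list shares 3 genes, Apoe, Lpl and Mertk, with the LXR targets, and its other 17 measured members had a median of 0.77 (0.62 to 1.07). In APCs other than the cells named macrophages, the median was 0.50 (0.30 to 0.66) over 16 measured genes, of which 7 were at least 1.5-fold higher; the LXR target median there was 1.04 (0.87 to 1.34). The cells named macrophages differed in depth and in ribosomal protein transcripts between the libraries: the 27 control cells had a median of 4415 UMIs with 26.2% of UMIs from ribosomal protein genes, and the 52 RGX-104 cells a median of 11398 UMIs with 10.9%.

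Inflammatory cytokines and chemokines had a median log2 ratio of 0.56 (0.43 to 0.66), with 13 of 26 measured members at least 1.5-fold higher and 1 lower. Nos2, the inducible nitric oxide synthase, had 0 UMIs in control APCs and 16.0 CPM in RGX-104 APCs, at least 38.9-fold higher against a floor of 3 counts; 144 of its 159 RGX-104 UMIs came from cells named macrophages and the other 15 from 2 cells. Ccl8, a monocyte chemokine, had a log2 ratio of 2.55, with 63.6% of its control UMIs and 29.3% of its RGX-104 UMIs from 1 cell each, and Il1a one of 2.49. Il12a, a subunit of interleukin 12, had one of -1.996. Outside the cells named macrophages the list median was 0.49 (0.31 to 0.58). Within the 6 compared types it was smaller, from -0.16 in mcDC2 to 0.35 in rcDC2. It lay above 0 in 4 of them and above its random range in 3.

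Interferon gamma response and class I presentation genes had a median of 0.13 (0.10 to 0.18) in all APCs, with 7 of 26 members at least 1.5-fold higher. Iigp1, an interferon-induced GTPase, was 13.8-fold higher (9.15 to 21.8), and 8.69-fold higher (5.72 to 13.8) outside the cells named macrophages. Gbp7, a guanylate-binding protein, had a log2 ratio of 2.22, and Cxcl10 and Cxcl9, chemokines that attract activated T cells, had 1.84 and 1.31. Among the 6 compared types the difference was largest in mono, where the median was 0.92 (0.66 to 1.26) and 14 of 25 measured members were at least 1.5-fold higher; Cxcl9 there stood at 51.4 CPM in control and 996 CPM in RGX-104 cells, 19.4-fold higher (13.3 to 29.4), with 78.6% of the control UMIs from 1 cell. In mcDC1 the median was -0.14, inside its random range. Type I interferon response genes had a median of 0.32 (0.07 to 0.35) in all APCs, with 3 of 29 at least 1.5-fold higher, Ifit2, Rtp4 and Zbp1 at 0.79, 0.77 and 0.61, and 1 lower, Bst2, also a marker of plasmacytoid dendritic cells (pDC), at -1.14. In mcDC1 the median of this list was -0.30 (-0.44 to -0.06), below its random range.

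Class II presentation genes were nearly level in all APCs pooled and differed between the types. The pooled median was 0.06 (0.05 to 0.13), with Ctsd, a lysosomal protease, at 1.66 and Ctsl, another, at -1.44. Outside the cells named macrophages the ratio of Ctsd was 1.007 (0.842 to 1.21). Without the cells named pDC, 0 of 15 measured members, Ctsl among them, were at least 1.5-fold lower. Among the types, the median was -0.72 (-0.83 to -0.56) in mcDC2, with 8 of 12 measured members at least 1.5-fold lower, and -0.33 (-0.39 to -0.20) in mcDC1, with 4 of 13 lower. It was -0.18 in mLC and 0.33 (0.27 to 0.40) in mono. H2-DMb2, a chain of the chaperone that loads peptides on class II molecules, was 3.71-fold lower (2.42 to 5.76) in RGX-104 mcDC2 and 2.69-fold lower (2.07 to 3.52) in mcDC1, and H2-Ab1, a class II chain, was 1.94-fold lower (1.76 to 2.14) in mcDC2, with 20.6% of its control and 21.1% of its RGX-104 UMIs from 1 cell each.

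Of the 22 lists measured in pooled APCs, 11 had medians above their random range and 1, the B cell list, below it. Among those not yet given, the mature migratory dendritic cell program, glycolysis, the cytotoxic list and the myeloid list lay above it. The mature migratory dendritic cell program had a median of 0.04, with Ccl17 and Cd274 highest at 1.04 and 0.72. Without the cells named pDC its median was -0.04 (-0.07 to 0.009). Glycolysis had 0.23 (0.16 to 0.33), oxidative phosphorylation -0.06 with a sign that depended on the scaling, proliferation -0.08 and the dissociation and stress response -0.09. T cell activation genes had -0.05, cytotoxic genes 0.10, inhibitory receptors -0.04, naive T cell genes -0.07, regulatory T cell genes 0.01 and follicular helper genes 0.04. Of the lists for other cell types, B cell genes had -0.33 (-0.78 to -0.11), led by Ly6d at -2.99, which pDC also express, and without the cells named pDC their median was 0.01. T cell markers had -0.15 and the myeloid list 0.13, both with a sign that depended on the setting, and stromal and endothelial genes -0.27 over 5 measured genes. Plasma cell, NK cell, neutrophil and erythroid lists had fewer than 5 measured members in APCs.

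The 8 genes ranked highest in APCs were Camp, Saa3, Elane, Prtn3, Gpnmb, Gdf15, S100a8 and Acod1. Saa3, an acute-phase apolipoprotein, was 166-fold higher (84.3 to 386), and 12.5-fold higher (6.14 to 29.5) outside the cells named macrophages. Gdf15, a stress-induced cytokine, was 26.8-fold higher (13.9 to 59.0), and Acod1, which makes itaconate, 25.1-fold higher (11.3 to 69.2). Outside those cells the ratios were 3.58 (0.999 to 19.4) for Gdf15, from 3 control and 14 RGX-104 UMIs, and 6.01 (2.56 to 17.2) for Acod1. Camp, Elane, Prtn3 and S100a8, products of neutrophils and their precursors, were also ranked, with 99.6%, 99.7%, 94.1% and 84.9% of their RGX-104 UMIs from 1 cell. The 8 with the lowest ratios were Cox6a2, Klk1, Ly6d, Siglech, Rpgrip1, Smim5, Atp1b1 and Eldr, of which Cox6a2, Klk1, Ly6d, Siglech and Smim5 are among 10 markers of pDC. Cox6a2, a muscle-type subunit of cytochrome c oxidase, was 10.3-fold lower (8.46 to 12.5) and Siglech, a surface lectin of pDC, 7.76-fold lower (6.74 to 8.96). With CPM averaged over the types at the same weights in both libraries, their log2 ratios were -0.35 and -0.16, and that of Eldr was 0.04.

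Among annotated APCs, pDC, the dendritic cells specialised in type I interferon release, made up a smaller share of the RGX-104 library. They were 53 of 782 control APCs, 6.78% (5.12 to 8.77, Clopper-Pearson), and 9 of 949 RGX-104 APCs, 0.948% (0.435 to 1.79), a 7.15-fold lower share (3.49 to 16.5). Barcodes without an annotation that carried at least 5 of 10 pDC markers numbered 13 in the control library and 20 in the RGX-104 library. Counted together with the annotated pDC, they were 0.898% of 7346 barcodes and 0.334% of 8671, a ratio of 0.372 (0.232 to 0.584).

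The cells named rcDC2 and mcDC2 made up larger shares of the RGX-104 library. Of APCs, rcDC2 were 11.1% in the control and 17.6% in the RGX-104 library, a ratio of 1.58 (1.21 to 2.07), and mcDC2 were 7.29% and 10.96%, a ratio of 1.503 (1.08 to 2.11). Cells named Gm26917+ mcDC were 1.53% and 3.37%, a ratio of 2.20 (1.10 to 4.69), with median depths of 1973 and 2048 UMIs. The mLC were 18.7% and 14.1%, a ratio of 0.756 (0.594 to 0.963). For the other 5 types the intervals included 1: macrophages at 1.59 (0.979 to 2.63), mcDC1 at 1.06, mono at 0.857, rcDC1 at 0.842 and pre-DC2 at 0.721.

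**Figure D2:**
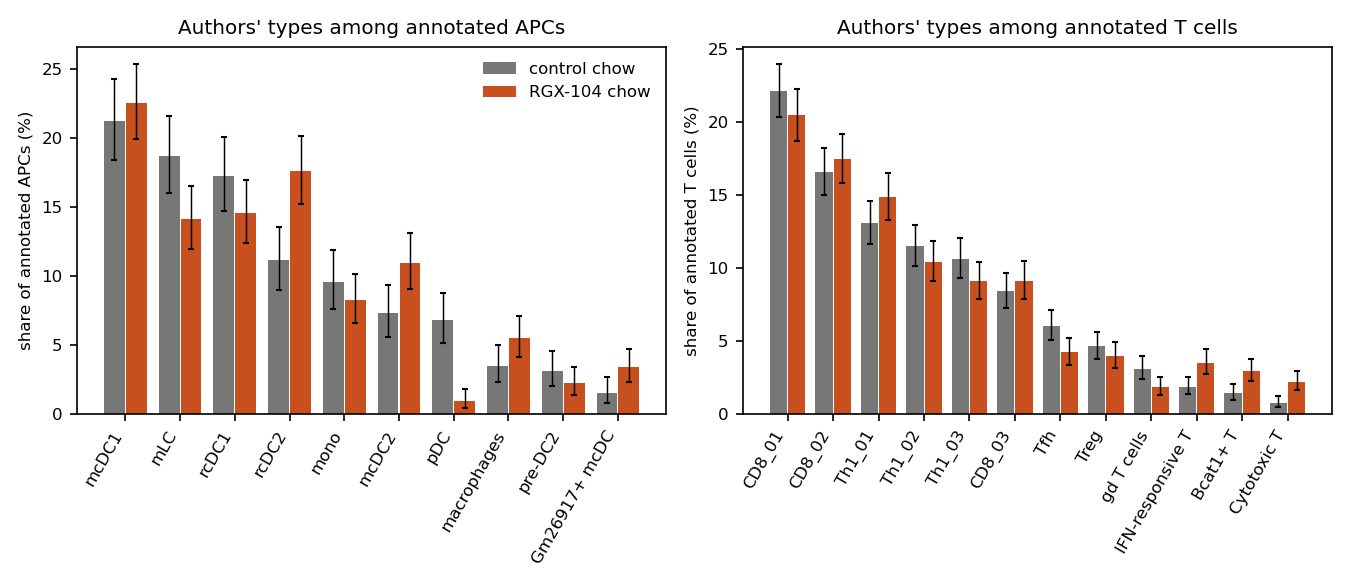
Share of each authors' type, in percent, among annotated APCs (left; 782 control and 949 RGX-104 cells) and annotated T cells (right; 2099 and 1995), with 95% Clopper-Pearson intervals as error bars, 1 library per chow. The bars for pDC stand at 6.78% and 0.948%, and those for Cytotoxic T at 0.762% and 2.21%.

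In T cells, genes of cholesterol synthesis and of LXR-driven lipid metabolism were higher in the RGX-104 library. Scd2 stood at 21.6 CPM in control and 278 CPM in RGX-104 T cells, a ratio of 12.8 (11.3 to 14.7), and Abca1 at 13.8 and 115 CPM, a ratio of 8.31 (7.04 to 9.87). Also ranked among the genes with the highest ratios were Srebf1 at 5.05-fold (4.46 to 5.75), Idi1, an isoprenoid isomerase, at 4.76-fold (4.005 to 5.70) and Insig1, a sterol sensor, at 4.45-fold (3.82 to 5.21). Gzma, granzyme A, was ranked with them at 5.13-fold (3.73 to 7.21), with 39.1% of its RGX-104 UMIs from 1 cell. Its interval lay above 1 in 0 of the 8 compared T cell types.

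Of 23 measured genes of cholesterol synthesis and uptake, 20 were at least 1.5-fold higher in RGX-104 T cells and 0 lower, with a median log2 ratio of 1.30 (1.18 to 1.501) against a random range of -0.10 to 0.09. Of 19 measured LXR targets, 14 were higher and 0 lower, with a median of 1.21 (0.99 to 1.34). Abcg1 was 3.07-fold higher (2.78 to 3.38) and Mylip 2.35-fold (2.12 to 2.60). Apoe, a transcript of macrophages, at 8674 CPM in the RGX-104 cells of that name, was 1.504-fold higher (1.15 to 1.98), with an interval above 1 in 3 of 8 types and a ratio of 0.115 (0.0226 to 0.366) in Tfh. Nr1h2 had a ratio of 1.07 (0.951 to 1.20), Nr1h3 was under 50 UMIs, and Ccr7, which retains T cells in the node, had a ratio of 0.798 (0.775 to 0.822). In T cells with both cell cycle scores under 0, the cholesterol median was 1.48 (1.29 to 1.71).

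Each of the 8 T cell types with at least 50 cells in each library showed both lists above the random range. The cholesterol median ran from 1.41 (1.05 to 1.79) in Tfh to 1.87 (1.45 to 2.34) in Th1_02, and the LXR target median from 0.98 (0.75 to 1.29) in Th1_02 to 1.69 (1.15 to 2.24) in Treg. Scd2 ran from 8.43-fold in Tfh to 18.0-fold in Th1_03, and Abca1 had intervals above 1 in all 8 types.

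**Figure D3:**
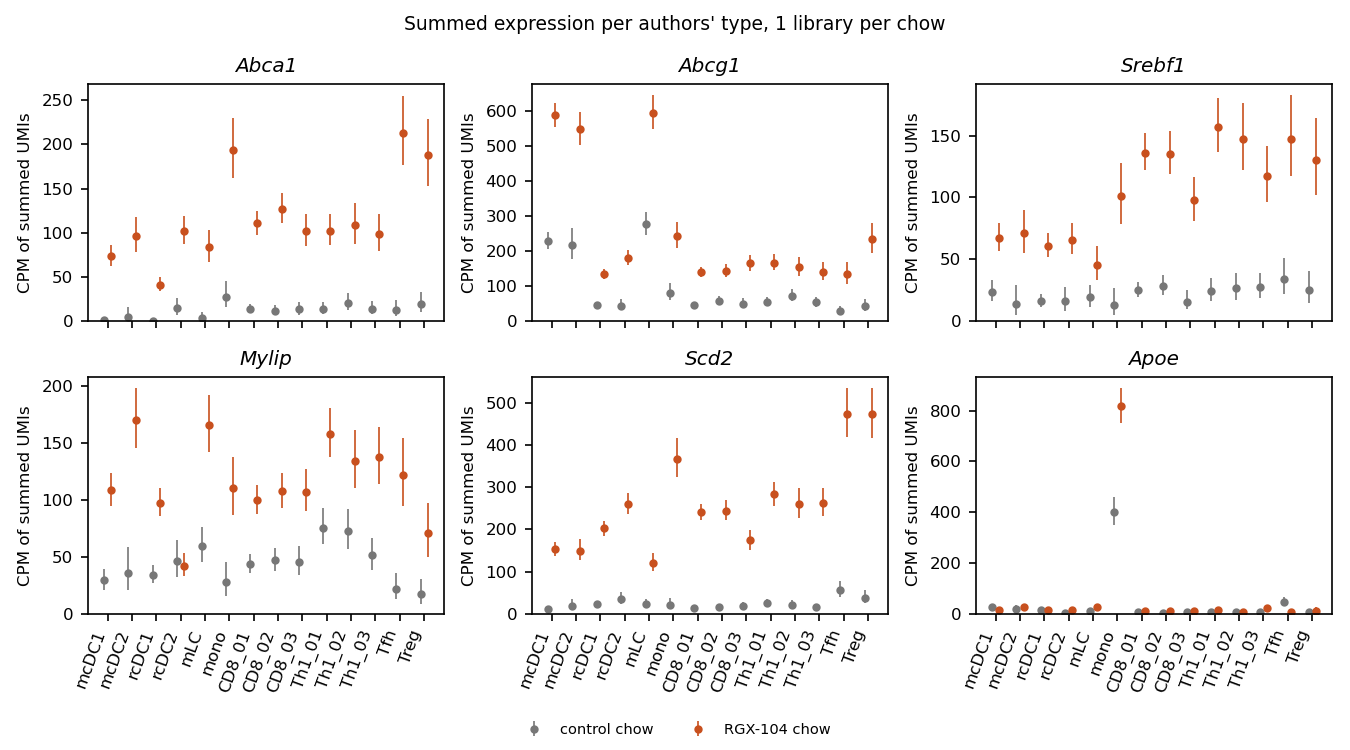
CPM of summed UMIs for Abca1, Abcg1, Srebf1, Mylip, Scd2 and Apoe in each compared type of the control (grey) and RGX-104 (orange) library; lines are 95% counting intervals, with 1 library per chow. The orange points lie above the grey ones in all 14 types for Abca1, Abcg1, Srebf1 and Scd2, and not for Mylip in rcDC2 (ratio 0.907) or Apoe in mcDC1 (ratio 0.530) and Tfh (ratio 0.115).

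Cytotoxic and effector genes had a median log2 ratio of 0.36 (0.26 to 0.49) in all T cells, with 9 of 28 measured members at least 1.5-fold higher and 1 lower. Gzma had 2.36, Ifng, interferon gamma, 2.26, with 29.1% of its RGX-104 UMIs from 1 cell, Ccl4, a chemokine of activated T cells, 2.02, and Gzmk, granzyme K, 1.70. In T cells other than those named Cytotoxic T, the median was 0.19 (0.09 to 0.26) and 5 members were higher. Proliferation genes had a median of 0.32 (0.24 to 0.36), with 7 of 28 higher, among them Ube2c, a mitotic ubiquitin-conjugating enzyme, at 1.36 and Ccnb1, cyclin B1, at 1.22. Without the cells named Cytotoxic T and Bcat1+ T, the median of that list was 0.07 (0.02 to 0.14).

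The medians of the dissociation and stress response list and of the regulatory T cell list lay below their random ranges in all T cells, each with a minority of members at least 1.5-fold lower. The dissociation and stress response list had a median of -0.19 (-0.26 to -0.15), with 3 of 20 measured members lower and 0 higher: Atf3, Jun and Fos, transcription factors induced within minutes of stimulation or handling, at -1.05, -0.86 and -0.77. Its median was below the random range in 11 of the 14 compared types of APCs and T cells. Cd69, an early activation antigen, was 1.91-fold lower (1.64 to 2.23) in CD8_02 and 2.02-fold lower (1.59 to 2.58) in Th1_03. The regulatory T cell list had a median of -0.21 (-0.34 to -0.14), with 4 of 20 at least 1.5-fold lower: the chemokine receptor Ccr8 at -0.73, Capg at -0.67, the lectin-like receptor Klrg1 at -0.62 and the integrin Itgae at -0.60. It lay below the random range in 2 of the 7 T cell types in which it was measured, and its median in CD8_01 was 0.18. Within Treg cells the median was -0.21 (-0.30 to -0.07).

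The remaining lists in T cells were as follows. Interferon gamma response genes had 0.17 (0.09 to 0.20), with Iigp1 at 1.59, and type I interferon genes 0.05. T cell activation genes had -0.09, inhibitory receptors -0.08, naive T cell genes -0.01, follicular helper genes -0.05, glycolysis 0.10, oxidative phosphorylation -0.03 with a sign that depended on the scaling, inflammatory cytokines 0.28 over 9 genes, macrophage lipid genes 0.19 over 6 genes and the mature dendritic cell program 0.01. Transcripts of other cell types were present as well: the myeloid list had a median of 0.54 (0.40 to 0.70), with H2-Aa at 26.7 and 55.7 CPM, Lyz2 at 11.8 and 19.5 CPM and Cd74 at 124 and 187 CPM in control and RGX-104 T cells, and the class II list, which shares 4 genes with it, had 0.07. NK cell genes had 0.37 over 6 genes, B cell genes 0.06 and T cell markers -0.09. Plasma cell, stromal, neutrophil and erythroid lists had fewer than 5 measured members. Of the 8 genes ranked lowest, the hemoglobin genes Hba-a1, Hbb-bs and Hba-a2 came from 1 control cell, and 92.5% of the control UMIs of the chemokine Ccl1 from 1 cell. The others were Actn2, an actinin, 2.004-fold lower (1.705 to 2.36), Jun 1.81-fold, Fos 1.71-fold and Tmem176b, a membrane protein, 1.79-fold lower.

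Among annotated T cells, the cells named Cytotoxic T, Bcat1+ T and IFN-responsive T made up larger shares of the RGX-104 library. Cytotoxic T were 16 of 2099 control cells, 0.762% (0.436 to 1.23), and 44 of 1995 RGX-104 cells, 2.21% (1.61 to 2.95), a ratio of 2.89 (1.60 to 5.49). Bcat1+ T were 1.43% and 2.91%, a ratio of 2.03 (1.29 to 3.27), and IFN-responsive T 1.86% and 3.51%, a ratio of 1.89 (1.26 to 2.87). Cells named Tfh, after the helpers of B cells, were 6.003% and 4.21%, a ratio of 0.701 (0.526 to 0.932). A larger part of the control than of the RGX-104 cells of that name carried Cd8b1, and the share without them was not computed. Cells named gamma delta T cells were 3.10% and 1.85%, a ratio of 0.599 (0.389 to 0.910). Of these, 16 of 65 control and 10 of 37 RGX-104 cells had both a productive TRA and a productive TRB chain. For the other 7 types the intervals included 1: CD8_01 at 0.925, CD8_02 at 1.05, CD8_03 at 1.09, Th1_01 at 1.14, Th1_02 at 0.908, Th1_03 at 0.854 and Treg at 0.857. With all barcodes as denominator CD8_02, CD8_03 and Th1_01 lay on the other side of 1, at 0.847, 0.876 and 0.915. The ratio of cells with Cd4 alone to cells with Cd8a or Cd8b1 alone was 0.547 in the control and 0.540 in the RGX-104 library.

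The TCR libraries asked whether clones of T cells were larger with LXR activation. A productive chain was found in 2415 control and 2438 RGX-104 barcodes, and both a TRA and a TRB chain in 1764 (73.0%) and 1549 (63.5%). Of the paired cells, 35 in the control library, 1.98% (1.39 to 2.75), and 61 in the RGX-104 library, 3.94% (3.03 to 5.03), belonged to clonotypes of at least 2 cells, a ratio of 1.98 (1.29 to 3.10). These cells formed 17 control and 28 RGX-104 clonotypes. The intervals of this and the following clonotype shares count cells of 1 clonotype as independent, so they are too narrow. Thinned to 1549 cells each, the shares were 1.75% and 3.94%, a ratio of 2.25, and with clonotypes from TRB alone they were 5.32% and 7.10%, a ratio of 1.33. The probability that a random pair of cells shared a clonotype was 0.00122% and 0.00342%, a ratio of 2.80, given without an interval because the pairs of 1 clonotype are not independent. The 10 most frequent clonotypes held 1.19% and 1.61% of cells, a ratio of 1.36 (0.728 to 2.55) before thinning and 1.21 after it, so a difference in it was not detectable at this depth.

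Clones were small in both libraries. The most frequent clonotype held 3 control cells and 5 RGX-104 cells, and all 5 of the latter lacked an annotation. Of the cells named CD8_01, CD8_02 or CD8_03, 0.649% (0.177 to 1.65) of 616 control and 3.07% (1.69 to 5.10) of 456 RGX-104 cells were in clonotypes of at least 2 cells, a ratio of 4.73 (1.48 to 19.7). These were 4 control cells in 2 clonotypes and 14 RGX-104 cells in 7. The interval counts the cells as independent and is too narrow. Within CD8_03 these were 0 of 82 control cells, with an interval that ends at 4.40%, and 6.67% (2.49 to 13.9) of 90. Within CD8_02 they were 0 of 222, with an interval that ends at 1.65%, and 2.61% (0.717 to 6.56) of 153. Within CD8_01 the shares were 1.28% and 0.939%, and 0.872% and 0.939% when thinned to 213 cells each. Tfh had 8.51% (3.75 to 16.1) of 94 and 3.39% (0.413 to 11.7) of 59, Treg 2 of 71 and 2 of 50 cells, and Th1_02 1.38% and 1.80%. Th1_01 and Th1_03 had 0 in both libraries.

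Use of the 22 TRBV labels differed by at most 2.16 percentage points. The label TRBV12-2+TRBV13-2 joins 2 genes that also had labels of their own. TRBV12-2 alone was at 3.46% of control and 3.16% of RGX-104 paired cells, and TRBV13-2 alone at 2.38% and 2.97%. The 3 TRBV labels with the largest differences were the joint TRBV12-2+TRBV13-2, at 9.52% of control and 7.36% of RGX-104 paired cells, a ratio of 0.773 (0.604 to 0.986), TRBV3 at 7.48% and 9.49%, a ratio of 1.27 (0.996 to 1.62), and TRBV29 at 4.02% and 6.004%, a ratio of 1.49 (1.08 to 2.06). TRBV31 came next, at 5.33% and 3.74%, a ratio of 0.703 (0.498 to 0.985). The chain of invariant NKT cells (TRAV11-TRAJ18) was found in 12 control and 11 RGX-104 cells, and that of MAIT cells (TRAV1-TRAJ33) in 5 and 1. There was 1 clonotype found in both libraries, with 1 cell in each.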

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

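Of the tests in this part, those of cell cycle scores and of unannotated pDC were planned before the result was seen, and the others were chosen only after it was seen.

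Barcodes that the authors did not annotate drew attention because the lists led there as well. With more than 800 genes and under 5% mitochondrial UMIs, 1320 control and 1728 RGX-104 barcodes qualified, of which 63.7% and 66.7% carried B cell transcripts. In them LXR targets had a median log2 ratio of 0.87 (0.70 to 1.09) and genes of cholesterol synthesis and uptake one of 1.05 (0.88 to 1.12), with Abca1, the cholesterol exporter, 4.51-fold higher (4.01 to 5.08). Macrophage lipid genes had 1.18 (0.86 to 1.40), and plasma cell genes, of which 4 of 7 were at least 1.5-fold lower, -1.14 (-1.42 to -0.83).

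Genes of cholesterol synthesis and uptake were higher in the RGX-104 library in APCs and in T cells. A shift in cell-type composition is argued against by the list lying above its random range in 14 of 14 compared types. More cycling cells are argued against by a median of 0.83 among APCs with both cycle scores under 0. A difference between the 2 libraries other than the chow could also raise these genes, and with 1 library per chow it stays open.

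The smaller share of pDC in the RGX-104 library has a counting interval that ends at 0.286, which argues against counting error. Some pDC may have been left out of the annotation: with marked barcodes added, the ratio of shares was 0.372 (0.232 to 0.584), nearer to 1 but still under it, and whether those barcodes are pDC was not settled. Of them, 11 of 13 control and 17 of 20 RGX-104 barcodes had at least 2 Siglech UMIs. At least 5 markers were also found in 15 of 729 control and 13 of 940 RGX-104 APCs annotated as other types. A difference in dissection or sorting between the 2 libraries stays open, since there was 1 library per chow.

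The deposited clonal frequency drew attention because it was above 1 for 25.8% of RGX-104 and 16.0% of control T cells with a chain, far more than the shares from nucleotide sequences of both chains. Cells with 1 of the 2 chains grouped by V and J genes hold 93.8% of this difference, and they were 35.6% of RGX-104 and 25.1% of control cells, so this explanation fits. At the control library's share of such cells the difference of 9.75 points would be 2.998 points. More clonal expansion with RGX-104 stays open as a further part, with 1 library per chow. By paired nucleotide sequences the ratio of shares in clonotypes of at least 2 cells was 1.98 (1.29 to 3.10) over all paired cells. Over annotated paired cells it was 1.86 (1.02 to 3.47). Over all annotated T cells with a chain, as for the deposited frequency, the ratio by deposited nucleotide sequences was 1.37 (0.845 to 2.24). In those with both chains it was 1.60 (0.854 to 3.04). Cells with both chains held 0.609 of the 9.75 points. These intervals count cells of 1 clonotype as independent and are too narrow.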

How the results depend on the processing

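No paired analysis was possible because there was 1 library per group and no pairing in the labels, and for the same reason no library could be left out in turn. Of 768 alternative values for 72 list medians, 688 stayed inside the counting interval of the value given, 74 moved out of it and 6 changed sign. Of 1066 for named genes, 949 stayed, 116 moved and 1 changed sign. Of 78 for shares, 70 stayed and 8 moved. Counted at 2-fold instead of 1.5-fold, 34 of 53 numbers of list members moved. All 23 for the TCR comparison stayed inside the counting intervals, which do not allow for dependence between cells of 1 clonotype or between pairs of cells. The thinned ratio of shares in clonotypes of at least 2 cells went from 2.25 to 1.33 with TRB alone and to 2.36 with annotated T cells alone.

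With the mean over cells of per-cell CPM, the cholesterol synthesis and uptake median in APCs was 0.96 instead of 0.81; the cause was not tested. With the mean over the authors' types of their medians it was 1.05 in APCs, and in T cells 1.66 instead of 1.30. The same setting gave class II presentation in APCs -0.17 instead of 0.06 and the myeloid list in APCs -0.080 instead of 0.13. It weighs each type by its number of cells over both libraries, leaves out types with few cells and picks measured genes per type. Which of these moved the values was not tested.

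With CPM averaged over the types with the same weights, a setting chosen after seeing the data, the macrophage lipid median in APCs was 0.71 instead of 1.15, and the log2 ratio of Eldr was 0.039 instead of -2.25. Both values lie nearer to 0 with the mix of types held the same.

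Oxidative phosphorylation, close to 0 throughout, changed sign in APCs from -0.06 to 0.0016 with TMM and 0.0016 with median-of-ratios factors, and in T cells from -0.03 to 0.00033 with totals without receptor, immunoglobulin, mitochondrial and ribosomal protein genes. With cells thinned to 2000 UMIs, T cell markers in APCs were at 0.041 instead of -0.15. The cause was not tested.

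With all barcodes as denominator, the ratios of shares were 0.745 for CD8_01, 0.847 for CD8_02, 0.876 for CD8_03, 0.915 for Th1_01, 0.731 for Th1_02 and 0.688 for Th1_03. Annotated T cells were 2099 of 7346 control and 1995 of 8671 RGX-104 barcodes, which by itself changes each of these ratios by the same factor. CD8_02, CD8_03 and Th1_01 turned to the other side of 1. Among T cells with paired chains, CD8_02 had 0.883 and CD8_03 1.41, and the cause was not tested.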

Other observations

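Proliferation genes differed between the types in both directions. In rcDC1 the median log2 ratio was 0.45 (0.25 to 0.47), with 7 of 28 measured members at least 1.5-fold higher in the RGX-104 library, among them Rrm2, a subunit of ribonucleotide reductase, 2.23-fold higher (1.61 to 3.15), and Mki67, a marker of cycling cells, 1.60-fold higher (1.34 to 1.91). In Treg it was -0.58 (-0.72 to -0.35), with 9 of 19 at least 1.5-fold lower, led by Stmn1, a microtubule regulator, 2.64-fold lower (2.11 to 3.34), while Mki67 there had a ratio of 0.901 (0.678 to 1.20). In Tfh the median was -0.44 (-0.64 to -0.15), and some of its members also rested on few cells. Mcm5 had 10 RGX-104 UMIs, 60% of them from 1 cell. Pclaf was found in 5 of 126 control and 5 of 84 RGX-104 cells, with 34.5% and 50% of its UMIs from 1 cell each. The medians of 0.72 in CD8_01 and -1.27 in mcDC2 stood beside a concentration of single genes in single cells: 71.1% of control and 71.8% of RGX-104 Mki67 UMIs in CD8_01, and 60.7% of the control UMIs of Top2a, a topoisomerase, in mcDC2, came from 1 cell each.

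Treg and Tfh also differed in single genes. In RGX-104 Treg the metallothionein Mt1 was 16.4-fold higher (6.05 to 62.2), with 45.5% of its RGX-104 UMIs from 1 cell. Nkg7, a cytotoxic granule protein, was 2.98-fold higher (2.14 to 4.19), carried by 16 of 97 control and 13 of 79 RGX-104 cells with 25.4% of the RGX-104 UMIs from 1 cell, and Klrg1 was 2.26-fold lower (1.46 to 3.59). In Tfh, Cd8b1 and Cd8a, which encode the CD8 chains and are foreign to helper cells, were 5.04-fold (3.49 to 7.51) and 4.54-fold (2.98 to 7.17) lower in the RGX-104 library, with Cd8b1 found in 27 of 126 control and 8 of 84 RGX-104 cells. In mono, Ly6a, an interferon-induced surface protein, was 6.51-fold higher (5.01 to 8.60) and Anxa1, annexin A1, 3.30-fold lower (2.25 to 4.92). In rcDC2, Lyz1, a lysozyme, was 52.7-fold higher (17.9 to 257), with 39.0% of its RGX-104 UMIs from 1 cell.

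The cells named macrophages were too few for the comparison of types, at 27 and 52, and differed in depth. T cell receptor and immunoglobulin transcripts, counted together, made up 0.232% of their UMIs in the control and 0.011% in the RGX-104 library. The share was 0.288% in control T cells and 0.183% in control pDC, and it does not tell which cells the transcripts came from. C1qc, a complement gene of macrophages, was found in 13 of the 27 and 46 of the 52. The ratios within them therefore compare cells that were not shown to be the same population. The median log2 ratio was 2.07 (1.56 to 2.56) for interferon gamma response genes and 2.03 (1.71 to 2.62) for inflammatory cytokines. Cxcl9 was 28.5-fold higher (16.3 to 55.3), Nr1h3, which encodes LXR alpha, 5.22-fold lower (3.60 to 7.61), and Apoe 2.30-fold higher (2.11 to 2.51). Clonotypes of at least 3 cells numbered 1 in the control and 3 in the RGX-104 library, and 1 of the latter, with TRBV10, consisted of 3 cells named Cytotoxic T.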
